A study of Rhodonia placenta with 24 samples.

How the data were processed

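Gene expression was measured by RNA sequencing in mycelium of Rhodonia (Postia) placenta, a brown-rot fungus, that is, one that degrades the cellulose and hemicellulose of wood while leaving most of the lignin modified in place. Per the labels' protocols, mycelium grown in a rich malt and yeast extract medium was moved to a basal salts medium holding no carbon source, 1% glucose, 1% cellobiose (the disaccharide of glucose that cellulose breaks down to) or 1% ground aspen wood. It was sampled at 15 h and at 72 h, with 3 bioreplicates for each of the 8 groups, 24 libraries in all. Total RNA was depleted of ribosomal RNA, made into strand-specific libraries and sequenced on a SOLiD instrument, per the labels' protocols. The labels call the samples bioreplicates and do not say whether each came from its own culture, so p-values measure the spread between these samples.

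The authors deposited a table of 17173 gene models of the first P. placenta assembly from the JGI (the Joint Genome Institute) against 24 library columns. Its name calls the values normalized CPM, that is, reads scaled to library size, and per the file headers each column is one library. The columns do not sum to a common total, so the deposited values are treated as a normalized signal: whole read counts divided by a scaled library size. In each of the 24 columns, 100% of the values were whole multiples of the smallest positive value, within 0.02 reads, so whole reads per model could be recovered. The scaling factors implied by the column totals ran from 0.812 to 1.29, with a geometric mean of 1. The submitters' processing notes name edgeR, with no version; the aligner, the counting program and the genome build are not given in the sources used here. The authors also deposited 3 tables comparing glucose, cellobiose and aspen with no carbon at 15 h, each over 13113 models. Per the file headers they hold a log2 fold change and an average log2 expression, a t score, a p-value and an adjusted p-value, under the column names that limma writes. In those deposited tables the t score is 0 wherever the absolute log2 fold change is under 1, the form that limma's treat test gives. Running voom and treat with a log2 minimum of 1 on the recovered reads of all 24 columns gave the deposited fold changes to within 3.35e-14.

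The assay design foresaw raw counts or CPM; since the values are normalized CPM, the main test was run on log2(normalized CPM + 1). A pseudocount of 1 understates the change of models with low levels. Models were tested when they reached a normalized CPM of at least 1 in at least 3 libraries, which left 13099 models. limma 3.58.1 in R 4.3.3 was fitted with a mean for each of the 8 groups and one spread shared by them, with a trend in the prior variance. All tests were two-sided, with Benjamini-Hochberg adjustment over the 13099 models within each comparison and a threshold of 0.05 on the adjusted p. "Rose" and "fell" mark models past that threshold. The 19 comparisons were each carbon source with no carbon at each time, the carbon sources with one another, 72 h with 15 h in each medium, and the difference between the 72 h and 15 h effects of each carbon source (the interaction). No column of per-sample values was left unused. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6; plots were drawn with matplotlib 3.10.9.

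The columns for cellobiose at 15 h, replicates 2 and 3, held identical values in all 17173 models. They were counted as 1 sample, so 23 distinct libraries entered the tests and cellobiose at 15 h had n = 2. Wherever a cellobiose 15 h library was left out, that group held 1 library, and the spread came from the other groups only. Recovered reads ran from 7.18 M (mega) to 19.8 M per library, and 1 read was worth 0.0508 to 0.137 normalized CPM. The 13099 tested models had a median level of 10.2 normalized CPM, and at the lower levels single reads set the precision.

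The deposited files do not pair the model identifiers with gene names or functions, and no annotation was used here. The 27 lists of gene functions fixed for wood decay, carbon use and stress matched 0 models, so no list could be tested, and models are given by identifier. The rule for named models took, in each comparison, the models with the largest change per direction among those past the threshold. All values of one group had to lie above all of the other, with a mean of at least 10 normalized CPM in the higher group. For the interactions no such separation was asked, and the mean of at least 10 could be in any of the groups compared. With no annotation the rule names at most 2 that rose and 2 that fell. The assembly was made from a dikaryon, which carries a pair of different nuclei, and many of its genes are present as near-identical allelic models. How reads matching such a pair were divided is not given in the sources used here, so the level of any one of these models is uncertain.

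The test was tried on simulated data first, with 100 models changed 2-fold and 100 changed 4-fold among 13099 in each of 5 runs. The changed models were drawn only from those with a mean of at least 5 normalized CPM without carbon. Each model had the same simulated spread in all groups. The rates below therefore do not cover models at lower levels, or groups and libraries with a wider spread. For glucose against no carbon at 15 h it recovered 97.4% of the 4-fold and 51.6% of the 2-fold changes, with 5.84% false calls. The same values were 92.6%, 38.0% and 3.85% for cellobiose at 15 h and 98.4%, 47.8% and 6.01% for aspen at 15 h. At 72 h they were 97.0%, 45.8% and 7.80% for glucose, 95.2%, 50.2% and 7.11% for cellobiose, and 95.8%, 43.6% and 9.34% for aspen. Comparisons with the same no-carbon libraries share their chance values, so overlaps are given with the number that independent lists would share, and correlations with those of 20 simulated sets of unchanged groups. The 3 control libraries cannot be split into parts of 2, so part of any excess may come from the shared controls.

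The groups, tests, named-model rule and the alternatives of no filter, a pseudocount of 0.25, quantile normalization, only the compared groups in the fit, a replicate block, each replicate left out and a 2-fold minimum for overlaps were set before the data were examined. Chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood test, TMM scaling) on the recovered reads, the identical columns entered as 2 libraries, voom with treat, and leaving out aspen 72 h replicate 3 and glucose 72 h replicate 1 together.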

Results

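Transcript levels of the brown-rot fungus P. placenta were compared between 4 carbon conditions, namely no carbon, glucose, cellobiose and aspen wood powder, at 15 h and 72 h after transfer. Each of the 8 groups had 3 libraries, except that 2 of the cellobiose 15 h columns were identical and were counted as 1 sample (n = 2). Recovered reads ranged from 7.18 M (mega) in aspen 72 h replicate 1 to 19.8 M in no carbon 15 h replicate 1. Of 17173 gene models, 15683 had a read in at least 1 library, 1490 were listed at 0 throughout and 13099 were tested. The files do not pair model identifiers with gene names. The most abundant model, jgi_Pospl1_127047_estExt_fgenesh3_pg_C_1100007, took at least 4.81% of the reads in every library but one. In aspen 72 h replicate 3 the top model was instead jgi_Pospl1_99452_fgenesh3_pg_61__8, with 6.97% of the reads.

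A pair of 72 h libraries stood apart from their groups in the number of models with reads. Aspen 72 h replicate 3 had reads in 12292 models from 13.7 M reads, whereas replicates 1 and 2 had reads in 14269 and 14474 models from 7.18 and 8.51 M reads. Glucose 72 h replicate 1 had reads in 13555 models, against 14769 and 14789 in the other two, and its top model took 5.59% of the reads against 12.5% and 12.8%. To a lesser degree, glucose 15 h replicate 1 was also low, with reads in 13899 models against 14384 and 14732 in replicates 2 and 3. It had 10.4 M reads, a depth at which cellobiose 72 h replicate 3 had reads in 14525 models. By correlation of log2 levels across models, which are not independent replicates, glucose and cellobiose libraries at 15 h were alike, with a mean r of 0.976 between the groups, 0.970 within glucose and 0.987 within cellobiose. At 72 h the aspen libraries were closest to the no-carbon libraries, with a mean r of 0.933, against 0.942 within aspen and 0.988 within no carbon. The value within aspen is lowered by replicate 3, whose mean r with the other two was 0.923. The first principal component held 33.0% of the variance and set no carbon and aspen at 72 h apart from the 15 h libraries. On the second, glucose 72 h replicate 3 lay at 37.4, beside cellobiose at 72 h (33.2 to 36.5). Glucose 72 h replicates 1 and 2 lay at 77.1 and 65.3, so replicate 1 is not the only glucose library that differs. At 15 h glucose replicate 1 lay at 17.6, against -2.47 and -9.01 for replicates 2 and 3.

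**Figure D1:**
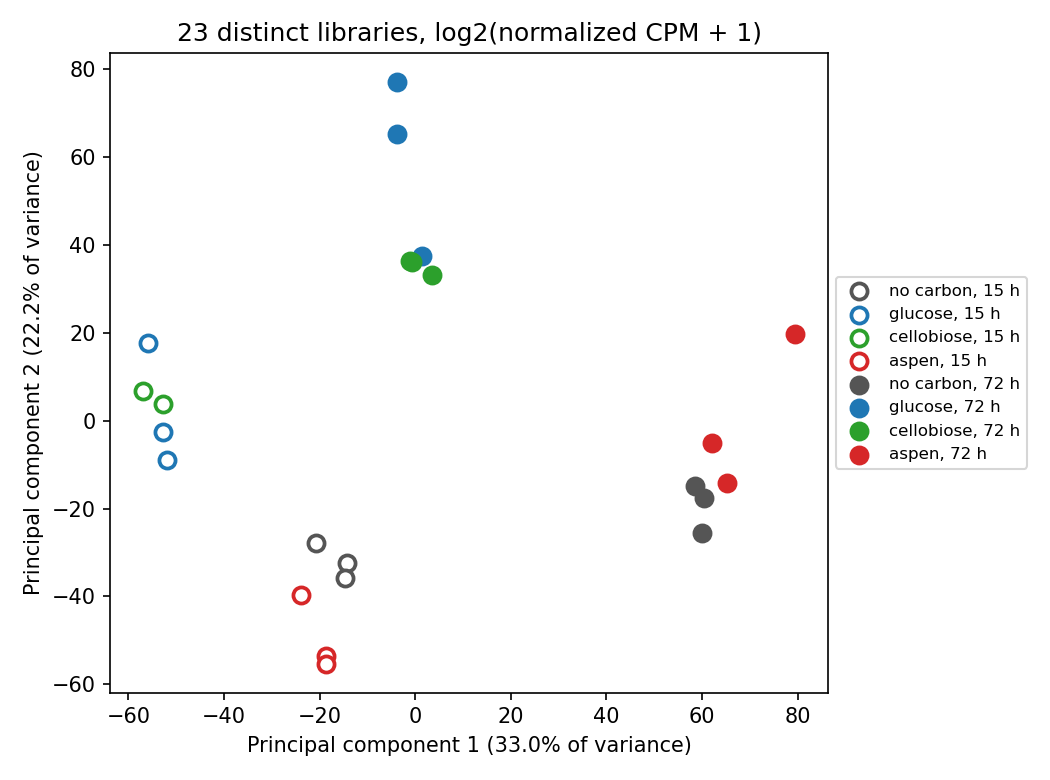
Principal components of log2(normalized CPM + 1) over 13099 models, each point 1 of the 23 distinct libraries, open at 15 h and filled at 72 h, with the first component (33.0% of the variance) on the horizontal and the second (22.2%) on the vertical axis. No carbon and aspen at 72 h lie at the right, glucose and cellobiose at 15 h at the left, and glucose and cellobiose at 72 h at the top.

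Glucose at 15 h lowered more models than it raised. Against no carbon, 1321 models fell and 927 rose, of which 655 and 351 changed at least 2-fold. The model with the largest fall, jgi_Pospl1_118723_estExt_Genewise1_C_180160, dropped from 1465 ± 294 (SD, n = 3) normalized CPM without carbon to 15.7 ± 5.18 (n = 3) in glucose, a log2 change of -6.49 ± 0.24 (SE; limma, adjusted p = 2.43e-15). jgi_Pospl1_93998_fgenesh3_pg_76__42 went from 196 ± 47.9 to 5.47 ± 0.998 (log2 change -4.91 ± 0.20; limma, adjusted p = 1.88e-14). Among risen models, jgi_Pospl1_51077_e_gw1_5_167_1 went from 1.09 ± 0.453 to 21.7 ± 14.2 normalized CPM and jgi_Pospl1_129282_estExt_fgenesh3_pg_C_1940024 from 4.69 ± 0.571 to 53.3 ± 11.5, log2 changes of 3.29 ± 0.39 and 3.23 ± 0.27 (limma, adjusted p = 1.56e-06 and 4.42e-09). The limma test called 2248 models and edgeR on the recovered reads 2319. The limma count was 1339 without no carbon 15 h replicate 1, 1160 without no carbon 15 h replicate 3, 1422 without glucose 15 h replicate 1, and 3856 when aspen 72 h replicate 3 and glucose 72 h replicate 1 were left out of the shared spread.

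Cellobiose at 15 h changed largely the models that glucose changed. Against no carbon 1184 models fell and 728 rose, 750 and 346 of them at least 2-fold. Of these, 907 also fell in glucose where independent lists would share 119, and 471 also rose where they would share 51.5. No model rose in glucose and fell in cellobiose, and 16 did the opposite; edgeR gave 0 and 17. jgi_Pospl1_118723_estExt_Genewise1_C_180160 and jgi_Pospl1_93998_fgenesh3_pg_76__42 led the fall here as well, at 14.4 ± 2.06 and 4.22 ± 0.137 normalized CPM in cellobiose (SD, n = 2), with log2 changes of -6.56 ± 0.27 and -5.20 ± 0.23 (limma, adjusted p = 2.35e-14 and 6.11e-14). jgi_Pospl1_54259_e_gw1_348_2_1 rose from 1.228 ± 0.348 to 60.9 ± 1.65 normalized CPM, and stood at 3.40 ± 0.341 in glucose. Its log2 change was 4.81 ± 0.29 and that of jgi_Pospl1_51077_e_gw1_5_167_1 was 3.34 ± 0.44 (limma, adjusted p = 1.41e-11 and 7.97e-06). Across models the glucose and cellobiose changes correlated with r = 0.854, against 0.448 in simulated unchanged groups with the same controls, and their covariance was 0.350 against 0.0405; part of the excess may still come from the shared controls. The test called 1912 models, and edgeR 1884 (890 risen, 994 fallen). That count was 642 without the repeated cellobiose library, 1234 without cellobiose replicate 1, 1174 and 1070 without no carbon 15 h replicates 1 and 3, 3163 with the identical columns as 2 libraries, 4559 with only the compared groups in the fit and 3324 without the pair of 72 h libraries that stood apart.

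The sets of models that moved in both sugars at 15 h were followed in the other conditions. Of the 907 that fell in both, 9.70% rose and 12.7% fell in aspen at 15 h, with a median log2 change of -0.04 there. At 72 h, 616 of the 907 were also lower in glucose than without carbon and 432 lower in cellobiose, while 52 and 88 were higher. Of the 471 that rose in both, 18 rose and 13 fell in aspen at 15 h, and 347 were higher in glucose at 72 h and 264 in cellobiose. Without carbon, 238 of the 471 fell between 15 h and 72 h and 27 rose.

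Few models told cellobiose from glucose at 15 h. limma called 47, of which 42 were higher in cellobiose and 5 lower, and edgeR called 43 higher and 1 lower. By limma 753 of the 13099 tested models had an unadjusted p under 0.05. A share of 0.05 of unchanged models would pass that threshold by chance, so the 753 do not count as further differences. jgi_Pospl1_115648_estExt_Genewise1Plus_C_1530060 stood at 570 ± 36.1 normalized CPM in cellobiose (SD, n = 2) and 30.97 ± 5.48 in glucose (n = 3), a log2 difference of 4.17 ± 0.24, and jgi_Pospl1_54259_e_gw1_348_2_1 differed by 3.82 ± 0.29 (limma, adjusted p = 4.87e-11 and 3.17e-09). Of the 42 higher models, 41 had risen in aspen at 15 h and 40 in aspen at 72 h, where independent lists would share 1.13 and 5.57. Their median log2 change in aspen against no carbon at 15 h was 3.47. In 39 of the 42 cellobiose was again higher than glucose at 72 h, where independent lists would share 3.60. Lower in cellobiose were jgi_Pospl1_129282_estExt_fgenesh3_pg_C_1940024, at 16.8 ± 1.804 against 53.3 ± 11.5, and jgi_Pospl1_130338_estExt_fgenesh3_pg_C_2750003, at 16.8 ± 1.64 against 53.3 ± 14.1, with log2 differences of -1.59 ± 0.30 and -1.58 ± 0.33 (limma, adjusted p = 0.00821 and 0.0249). Both lost the call under some settings, with an adjusted p of up to 0.292 for jgi_Pospl1_129282_estExt_fgenesh3_pg_C_1940024 without the repeated cellobiose library and up to 0.392 for jgi_Pospl1_130338_estExt_fgenesh3_pg_C_2750003 without cellobiose replicate 1. With the identical columns as 2 libraries, 78 models were called.

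Aspen at 15 h changed fewer models than either sugar, and more of them upward. Against no carbon 351 rose and 247 fell, 231 and 145 of them at least 2-fold. jgi_Pospl1_105534_fgenesh3_pg_151__35 rose from 23.6 ± 4.22 to 2966 ± 501 normalized CPM (SD, n = 3 each), while glucose libraries held 10.1 ± 2.05 and cellobiose libraries 90.5 ± 11.9. jgi_Pospl1_95807_fgenesh3_pg_58__36 rose from 2.33 ± 0.364 to 313 ± 44.5. The log2 changes were 6.92 ± 0.20 and 6.56 ± 0.25 (limma, adjusted p = 1.18e-17 and 1.15e-15). jgi_Pospl1_126338_estExt_fgenesh3_pg_C_1810001 fell from 34.8 ± 11.3 to 0.774 ± 0.112, and jgi_Pospl1_130016_estExt_fgenesh3_pg_C_1740011 from 238 ± 51.5 to 16.99 ± 3.39, with log2 changes of -4.29 ± 0.24 and -3.73 ± 0.32 (limma, adjusted p = 3.22e-12 and 6.96e-09). The test called 598 models, edgeR 600. With only the aspen and no-carbon groups in the fit it called 1074, and without the pair of 72 h libraries that stood apart 936.

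Models raised by aspen were often lowered by glucose. Of the 351, 148 fell in glucose at 15 h where independent lists would share 35.4, and 25 rose; the median log2 change in glucose was -0.47. Shared controls push such overlaps the other way. In cellobiose 96 of the 351 fell, 55 rose, and the median was -0.14. Among the 74 models raised at least 4-fold by aspen, 48 fell and 1 rose in glucose, whereas 18 fell and 24 rose in cellobiose. A set of 88 models rose in aspen and fell in both sugars at 15 h, and at 72 h 50 of them were higher in aspen than without carbon, 79 lower in glucose and 62 lower in cellobiose. Many of the models that fell in aspen also fell in the sugars. Of the 247, 49.0% (121 models) were also down in glucose and 54.3% in cellobiose. The remaining models rose or had no call in that sugar. Independent lists would share 24.9 and 22.3 fallen models, and here the shared controls push the overlap up. Across models the aspen and glucose changes correlated with r = -0.0492, where shared controls alone gave 0.504, and their covariance was -0.0146 against a simulated 0.0408. Aspen and cellobiose gave r = 0.120 against a simulated 0.447, and a covariance of 0.0368 against 0.0404, close to that of unchanged groups.

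**Figure D2:**
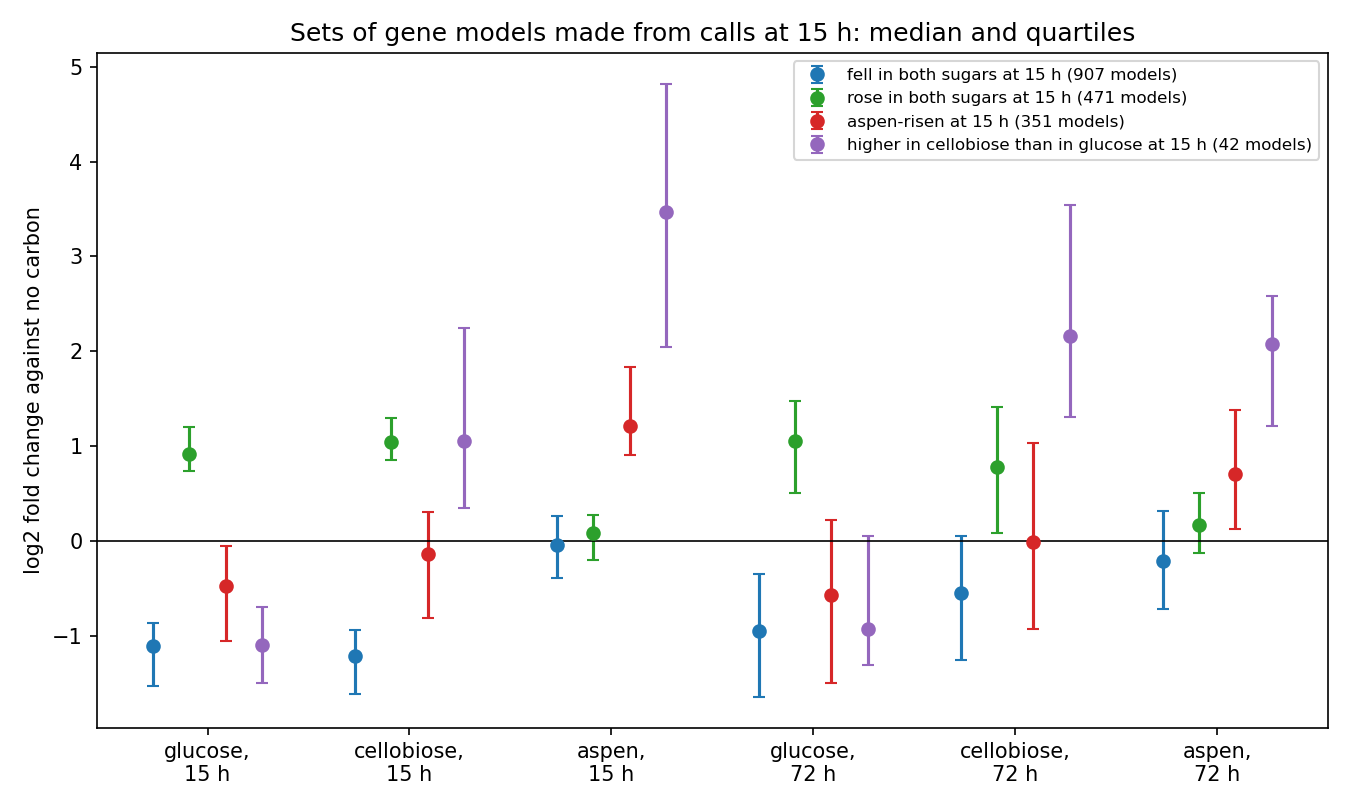
Median log2 fold change against no carbon (points, vertical axis) and its quartiles over models (bars) for glucose, cellobiose and aspen at 15 h and 72 h, in 4 sets of 907, 471, 351 and 42 models chosen by their 15 h calls. The 351 aspen-risen models have a median of -0.47 in glucose at 15 h, and the 42 models higher in cellobiose than in glucose have a median of 3.47 in aspen.

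Set directly against the sugars at 15 h, aspen libraries had 1752 models higher and 1631 lower than glucose libraries, and 1476 higher and 1025 lower than cellobiose libraries. jgi_Pospl1_127220_estExt_fgenesh3_pg_C_160041 stood at 1405 ± 32.8 normalized CPM in aspen (SD, n = 3), 284 ± 62.4 without carbon, 8.38 ± 1.05 in glucose and 7.80 ± 0.249 in cellobiose (n = 2). It exceeded glucose by 7.23 ± 0.17 and cellobiose by 7.32 ± 0.19 on the log2 scale, and jgi_Pospl1_105534_fgenesh3_pg_151__35 exceeded glucose by 8.07 ± 0.20 (limma, adjusted p = 1.70e-19, 2.10e-18 and 1.70e-19). jgi_Pospl1_90928_fgenesh3_pg_29__36 was lower, at 3.16 ± 0.609 in aspen, 153 ± 12.5 in glucose and 70.2 ± 9.90 in cellobiose, with log2 differences of -5.22 ± 0.22 and -4.10 ± 0.24 (limma, adjusted p = 1.79e-15 and 4.84e-12). By edgeR 3348 and 2447 models differed, against 3383 and 2501 by limma, and the balance of directions depended on scaling: quantile normalization gave 1613 higher and 1823 lower than glucose, and 1298 and 1254 than cellobiose. The comparison with cellobiose called 1034 models without the repeated cellobiose library, 1636 without aspen 15 h replicate 1 and 3945 without the pair of 72 h libraries that stood apart.

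In the authors' deposited tables for 15 h, 175 models passed an adjusted p of 0.05 in glucose (24 up, 151 down), 204 in cellobiose (38 up, 166 down) and 131 in aspen (99 up, 32 down). All of these were called here in the same direction. The authors' deposited table gives jgi_Pospl1_118723_estExt_Genewise1_C_180160 a log2 fold change of -6.56 in glucose and -6.61 in cellobiose, and jgi_Pospl1_105534_fgenesh3_pg_151__35 one of 6.97 in aspen. Across models the deposited fold changes and those computed here correlated with r = 0.941, 0.941 and 0.940. The deposited test asks for a change beyond 2-fold and entered the identical cellobiose columns as separate libraries; with 23 distinct libraries the same procedure called 170, 147 and 121.

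At 72 h many more models were called in the sugars than at 15 h. Against no carbon 2488 models rose and 3003 fell in glucose, and 2607 rose and 2647 fell in cellobiose. The sugars shared 1705 risen and 1796 fallen models, where independent lists would share 495 and 607, while 17 models rose in glucose and fell in cellobiose and 25 did the opposite. Their changes correlated across models with r = 0.792, against 0.500 in simulated unchanged groups with the same controls. jgi_Pospl1_112658_estExt_Genewise1Plus_C_1070028 rose from 37.2 ± 9.03 normalized CPM without carbon to 1748 ± 415 in glucose and stood at 2950 ± 908 in cellobiose (SD, n = 3 each). jgi_Pospl1_106722_fgenesh3_pg_54__24 rose from 1.799 ± 0.261 to 128.1 ± 23.7 in glucose and 341 ± 57.3 in cellobiose. Their log2 changes in glucose were 5.51 ± 0.22 and 5.51 ± 0.24 (limma, adjusted p = 4.55e-15 and 1.58e-14), and that of jgi_Pospl1_106722_fgenesh3_pg_54__24 in cellobiose was 6.92 ± 0.24 (limma, adjusted p = 4.00e-16). jgi_Pospl1_118723_estExt_Genewise1_C_180160 was again low, at 38.5 ± 8.33 in glucose and 30.3 ± 3.44 in cellobiose against 3767 ± 305 without carbon, and jgi_Pospl1_114469_estExt_Genewise1Plus_C_440067 stood at 4.32 ± 0.111 and 4.98 ± 0.896 against 499 ± 70.7. The latter had log2 changes of -6.55 ± 0.20 and -6.39 ± 0.20 (limma, adjusted p = 3.55e-17 and 6.22e-17). By edgeR 5272 and 5104 models were called, against 5491 and 5254 by limma. Quantile normalization turned the balance of directions, with 3019 risen and 2809 fallen in glucose and 2986 and 2615 in cellobiose.

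Many sugar responses of 15 h were still present at 72 h. Of the 927 models glucose had raised at 15 h, 524 were raised at 72 h, and of the 1321 it had lowered, 792 were lowered, where independent lists would share 176 and 303. In cellobiose 421 of 728 and 561 of 1184 were shared, against 145 and 239. These comparisons have no library in common, and their changes correlated across models with r = 0.529 in glucose and 0.414 in cellobiose.

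More models told cellobiose from glucose at 72 h than at 15 h, though the change over time in this difference was not tested. limma called 1123 models higher and 1155 lower in cellobiose, with 267 and 701 of them differing at least 2-fold; edgeR called 791 higher and 1239 lower, so that the share of higher models went from 49.3% to 39.0%. jgi_Pospl1_87727_fgenesh3_pm_20__3 stood at 270 ± 15.2 normalized CPM in cellobiose and 2.57 ± 0.471 in glucose, and jgi_Pospl1_107061_estExt_fgenesh3_pm_C_820005 at 145 ± 4.79 and 2.45 ± 0.870 (SD, n = 3 each). Both were higher still in aspen at 15 h, at 839 ± 98.9 and 706 ± 18.5. The log2 differences were 6.25 ± 0.24 and 5.44 ± 0.20 (limma, adjusted p = 3.98e-15 and 2.58e-15). jgi_Pospl1_126738_estExt_fgenesh3_pg_C_1790010 was lower in cellobiose, at 357 ± 83.9 against 2902 ± 781, a log2 difference of -3.01 ± 0.39 (limma, adjusted p = 1.78e-05). Of the 1123 models higher in cellobiose, 156 had risen in aspen at 15 h where independent lists would share 30.1, and 25 had fallen. The overlap with aspen at 72 h was weaker. There 257 of the 1123 had risen in aspen and 116 had fallen, where independent lists would share 149 and 145. Across all models this difference correlated with the aspen change with r = 0.294 at 15 h and r = -0.0301 at 72 h. The limma count of 2278 was 1009 without glucose 72 h replicate 1, which had reads in fewer models. It was 1945 and 3261 without glucose 72 h replicates 2 and 3, and 1409, 1486 and 925 without cellobiose 72 h replicates 1, 2 and 3. With only these groups in the fit it was 1389.

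Aspen at 72 h differed from no carbon in 1737 risen and 1695 fallen models, 683 and 798 of them at least 2-fold. jgi_Pospl1_105534_fgenesh3_pg_151__35 stayed high, at 3832 ± 734 normalized CPM against 184 ± 17.2 without carbon, and jgi_Pospl1_127853_estExt_fgenesh3_pg_C_150015 stood at 1997 ± 821 against 94.99 ± 32.6 (SD, n = 3 each). Their log2 changes were 4.36 ± 0.20 and 4.33 ± 0.41 (limma, adjusted p = 4.09e-13 and 4.51e-08). jgi_Pospl1_52765_e_gw1_302_22_1 fell from 21.3 ± 3.51 to 2.40 ± 1.77 while glucose and cellobiose held 107 ± 7.62 and 120 ± 3.14, and jgi_Pospl1_130030_estExt_fgenesh3_pg_C_520023 fell from 11.4 ± 1.35 to 1.06 ± 0.583. The log2 changes were -2.89 ± 0.30 and -2.62 ± 0.24 (limma, adjusted p = 3.01e-07 and 2.37e-08). Of the 351 models that aspen had raised at 15 h, 194 were raised at 72 h where independent lists would share 46.5, and 8 were lowered; of the 247 it had lowered, 69 were raised and 49 lowered. At 72 h aspen shared 781 risen and 951 fallen models with glucose, against 330 and 389 for independent lists, and 851 and 734 with cellobiose, against 346 and 343. The covariances of 0.214 with glucose and 0.201 with cellobiose exceeded the 0.0405 and 0.0407 of simulated unchanged groups, although the correlations of 0.334 and 0.313 did not exceed their 0.500 and 0.501; part of this sharing may come from the shared controls. limma called 3432 models and edgeR 2851 (1671 risen, 1180 fallen), so that the risen share was 50.6% and 58.6%; with quantile normalization 1737 rose and 1795 fell. The limma count was 1936 without aspen 72 h replicate 3, which stood apart, 2065 and 2139 without no carbon 72 h replicates 1 and 3, and 1323 with only these groups in the fit.

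Against the sugars at 72 h, aspen had 2177 models higher and 2047 lower than glucose, and 2375 higher and 2602 lower than cellobiose. jgi_Pospl1_130509_estExt_fgenesh3_pg_C_2310007 stood at 10827 ± 4275 normalized CPM in aspen, 787 ± 228 without carbon, 23.1 ± 5.49 in glucose and 27.5 ± 2.38 in cellobiose (SD, n = 3 each). jgi_Pospl1_109291_estExt_Genewise1Plus_C_1810018 stood at 467 ± 94.4 in aspen, 60.9 ± 12.8 without carbon and below 1 in both sugars. Aspen exceeded glucose by 8.75 ± 0.43 and 7.94 ± 0.22 on the log2 scale in these models (limma, adjusted p = 6.93e-14 and 2.69e-18). jgi_Pospl1_127978_estExt_fgenesh3_pg_C_1090044 was lower in aspen, at 12.3 ± 2.55 against 436 ± 105.1 in glucose, a log2 difference of -5.03 ± 0.18 (limma, adjusted p = 2.33e-16). By edgeR 3850 and 4564 models differed, against 4224 and 4977 by limma, and the balance turned to 2005 higher and 2333 lower than glucose with quantile normalization and to 2417 and 2147 than cellobiose by edgeR. With only aspen and glucose at 72 h in the fit 1712 were called, and both these groups hold a library that stood apart.

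**Figure D3:**
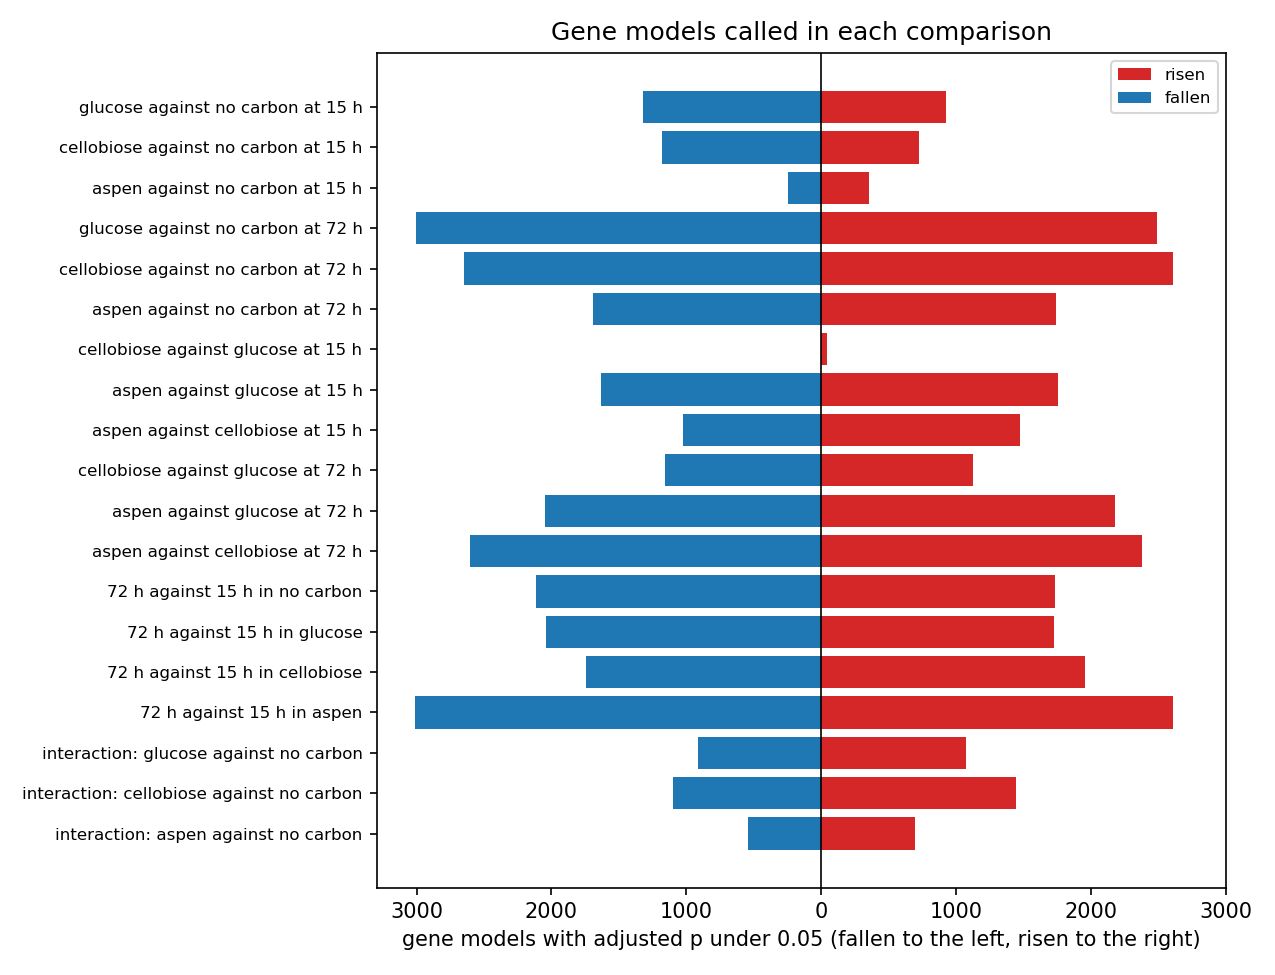
Numbers of models called by limma at an adjusted p under 0.05 (horizontal axis) in the 19 comparisons (vertical axis), with risen models drawn to the right and fallen models to the left of 0. The counts run from 47 for cellobiose against glucose at 15 h to 5622 for 72 h against 15 h in aspen.

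Without any carbon source the transcriptome also shifted between 15 h and 72 h, with 1735 models rising and 2117 falling. jgi_Pospl1_116469_estExt_Genewise1Plus_C_750050 rose from 1.65 ± 0.223 to 596 ± 114.7 normalized CPM and jgi_Pospl1_127594_estExt_fgenesh3_pg_C_1750010 from 0.638 ± 0.244 to 329 ± 30.7 (SD, n = 3 each), log2 changes of 7.80 ± 0.21 and 7.66 ± 0.28 (limma, adjusted p = 3.80e-18 and 7.88e-16). At 72 h the former stood at 453 ± 80.1 in aspen, 11.2 ± 2.70 in glucose and 21.8 ± 3.20 in cellobiose. jgi_Pospl1_129826_estExt_fgenesh3_pg_C_5740002 fell from 2049 ± 133 to 88.4 ± 11.5, a log2 change of -4.53 ± 0.59 (limma, adjusted p = 2.64e-06). Of the 1735 rising models, 1141 also rose over time in aspen, 663 in glucose and 693 in cellobiose. At 72 h 1010 of them were lower in glucose than without carbon and 1078 lower in cellobiose, against 391 in aspen. Of the 2117 falling models, 1131 were higher in glucose at 72 h than without carbon, 1397 in cellobiose and 670 in aspen. These counts against no carbon at 72 h use the libraries that defined the sets, so chance differences in those libraries push them in these directions. The test called 3852 models and edgeR 3766, and 6813 were called with only the no-carbon groups in the fit.

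Over the same interval 1726 models rose and 2039 fell in glucose, 1957 rose and 1744 fell in cellobiose, and 2610 rose and 3012 fell in aspen. jgi_Pospl1_121191_estExt_Genewise1_C_650017 rose in both sugars, from 7.34 ± 1.44 to 2783 ± 1225 normalized CPM in glucose (SD, n = 3) and from 40.2 ± 5.79 (n = 2) to 4317 ± 918 (n = 3) in cellobiose, log2 changes of 8.30 ± 0.26 and 6.70 ± 0.29 (limma, adjusted p = 5.34e-17 and 3.52e-14). In aspen jgi_Pospl1_130016_estExt_fgenesh3_pg_C_1740011 rose from 16.99 ± 3.39 to 24537 ± 11075 and jgi_Pospl1_113186_estExt_Genewise1Plus_C_670048 from 0.876 ± 0.0573 to 1212 ± 53.7, log2 changes of 10.34 ± 0.32 and 9.34 ± 0.21 (limma, adjusted p = 8.88e-18 and 1.01e-19). jgi_Pospl1_109291_estExt_Genewise1Plus_C_1810018 fell over time in glucose, from 54.9 ± 13.1 to 0.899 ± 0.335, and in cellobiose, from 23.2 ± 6.57 to 0.723 ± 0.424, with log2 changes of -4.87 ± 0.22 and -3.81 ± 0.25 (limma, adjusted p = 3.53e-14 and 2.48e-11). In aspen jgi_Pospl1_111395_estExt_Genewise1Plus_C_710082 fell from 1096 ± 148 to 75.6 ± 10.6, a log2 change of -3.84 ± 0.19 (limma, adjusted p = 1.35e-13). Of the 351 models raised by aspen at 15 h, 211 fell over time in aspen and 59 rose, and of the 247 it had lowered 174 rose and 27 fell. Because the 15 h aspen libraries defined these sets, part of that return may be chance in those libraries. By edgeR 3495, 3532 and 5217 models changed over time in glucose, cellobiose and aspen, against 3765, 3701 and 5622 by limma, and the balance of directions turned in each, with 1808 risen and 1687 fallen in glucose, 1687 and 1845 in cellobiose and 2686 and 2531 in aspen. With only the compared groups in the fit these were 1880, 6139 and 3730, and without the repeated cellobiose library 2029 changed in cellobiose.

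The change between 15 h and 72 h was compared with that of the no-carbon libraries through the interaction. Relative to no carbon, 1073 models had a higher glucose effect at 72 h than at 15 h and 910 a lower one. For cellobiose these numbers were 1443 and 1102, and for aspen 695 and 544. jgi_Pospl1_112658_estExt_Genewise1Plus_C_1070028 had the largest gain in glucose, 5.74 ± 0.32 on the log2 scale, and jgi_Pospl1_114469_estExt_Genewise1Plus_C_440067 the largest loss, -6.39 ± 0.28 (limma, adjusted p = 9.66e-12 and 2.70e-13). The latter rose from 2.72 ± 0.505 to 499 ± 70.7 normalized CPM without carbon and stood at 823 ± 116 in aspen at 72 h, against 4.32 ± 0.111 in glucose. For aspen jgi_Pospl1_90928_fgenesh3_pg_29__36 gained 7.11 ± 0.31, falling from 36.7 ± 6.06 to 5.92 ± 0.669 without carbon while going from 3.16 ± 0.609 to 105.3 ± 16.1 in aspen (limma, adjusted p = 1.55e-13). By edgeR 1923, 2347 and 1011 models were called for glucose, cellobiose and aspen, against 1983, 2545 and 1239 by limma. The cellobiose count was 1630 without the repeated library, 3992 without the pair of 72 h libraries that stood apart and 5470 with only the compared groups in the fit. The aspen count was 700 and 712 without no carbon 15 h replicates 1 and 2, 747 and 683 without no carbon 72 h replicates 1 and 3, 695 and 659 without aspen 15 h replicates 1 and 2, and 2289 without aspen 72 h replicate 2.

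**Figure D4:**
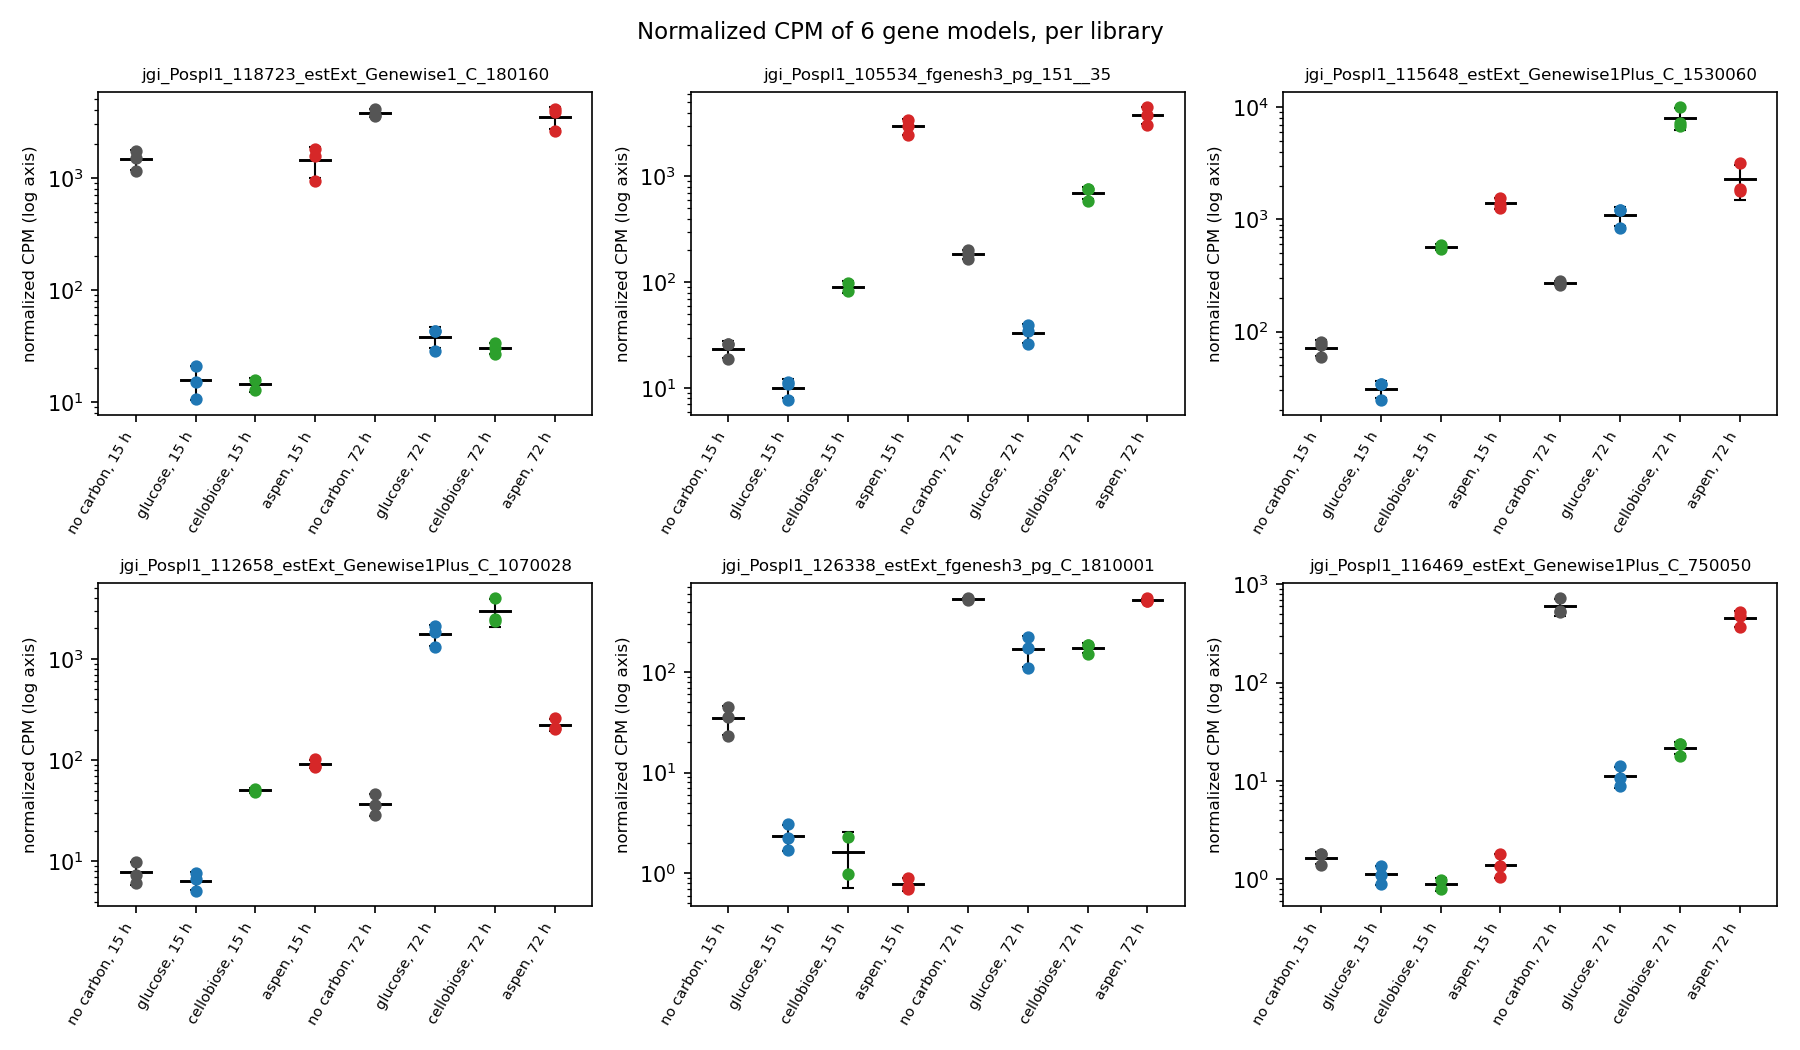
Normalized CPM on a log axis (vertical) of 6 models in the 8 groups (horizontal), with points for libraries, a bar at the mean and error bars of 1 SD. The models are jgi_Pospl1_118723_estExt_Genewise1_C_180160, jgi_Pospl1_105534_fgenesh3_pg_151__35, jgi_Pospl1_115648_estExt_Genewise1Plus_C_1530060, jgi_Pospl1_112658_estExt_Genewise1Plus_C_1070028, jgi_Pospl1_126338_estExt_fgenesh3_pg_C_1810001 and jgi_Pospl1_116469_estExt_Genewise1Plus_C_750050. The first stands at 1465 without carbon at 15 h and 15.7 in glucose, and the second at 2966 in aspen at 15 h.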

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

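All results here were marked because the effect of a carbon source against no carbon differed between 72 h and 15 h, tested by the interaction in limma; the interaction was chosen before the data were examined, and the counts of other splits after. Values are the 72 h effect minus the 15 h effect on the log2 scale. The interaction called 1983 models for glucose, 2545 for cellobiose and 1239 for aspen.

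For glucose the difference was 5.74 in jgi_Pospl1_112658_estExt_Genewise1Plus_C_1070028, 5.04 in jgi_Pospl1_127978_estExt_fgenesh3_pg_C_1090044, -6.39 in jgi_Pospl1_114469_estExt_Genewise1Plus_C_440067 and -5.29 in jgi_Pospl1_116469_estExt_Genewise1Plus_C_750050. It was 4.76 in jgi_Pospl1_106722_fgenesh3_pg_54__24, 1.33 in jgi_Pospl1_93998_fgenesh3_pg_76__42 and -1.67 in jgi_Pospl1_51077_e_gw1_5_167_1 (limma, adjusted p = 1.09e-09, 0.00250 and 0.0444).

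For cellobiose the difference was 6.14 in jgi_Pospl1_106722_fgenesh3_pg_54__24, 6.09 in jgi_Pospl1_106309_fgenesh3_pg_24__18, -6.09 in jgi_Pospl1_114469_estExt_Genewise1Plus_C_440067 and -5.95 in jgi_Pospl1_106359_fgenesh3_pg_24__68. It was 1.96 in jgi_Pospl1_54259_e_gw1_348_2_1, 1.76 in jgi_Pospl1_93998_fgenesh3_pg_76__42 and -3.25 in jgi_Pospl1_51077_e_gw1_5_167_1 (limma, adjusted p = 0.000883, 0.000254 and 0.000398).

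For aspen the difference was 7.11 in jgi_Pospl1_90928_fgenesh3_pg_29__36, 6.53 in jgi_Pospl1_109291_estExt_Genewise1Plus_C_1810018, -4.07 in jgi_Pospl1_95807_fgenesh3_pg_58__36 and -3.80 in jgi_Pospl1_51213_e_gw1_5_119_1. It was 5.56 in jgi_Pospl1_127853_estExt_fgenesh3_pg_C_150015, -3.08 in jgi_Pospl1_52765_e_gw1_302_22_1 and -2.42 in jgi_Pospl1_130030_estExt_fgenesh3_pg_C_520023 (limma, adjusted p = 4.65e-07, 3.29e-05 and 2.80e-05). Among the models that aspen changed most at 15 h it was -2.55 in jgi_Pospl1_105534_fgenesh3_pg_151__35, 4.25 in jgi_Pospl1_126338_estExt_fgenesh3_pg_C_1810001 and 4.11 in jgi_Pospl1_130016_estExt_fgenesh3_pg_C_1740011 (limma, adjusted p = 9.82e-07, 1.33e-08 and 1.03e-06).

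The interaction counts were set against other splits of the same 12 libraries, drawn at random, with the real division counted among the 100. For glucose 10 of the 100, the real division included, reached the real count of 1983, the highest with 5615 models. For aspen 2 of the 100, again with the real division included, reached 1239, the highest with 1757. In the highest split of each, the no-carbon libraries of 15 h were joined with the carbon-fed libraries of 72 h, which adds the carbon effects of both times into one contrast. Such splits carry real carbon effects and reflect a structure of the samples, so neither count decides on a division of the libraries by chance.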

How the results depend on the processing

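The named models kept their direction in every alternative: of 1164 values for 76 named-model results, 1151 kept their call, 13 lost it and 0 reversed. These models were chosen from the same libraries as the largest changes past the threshold, which favours keeping the call. The result does not extend to all called models, and the balance of risen and fallen models turned in several comparisons, as given above. edgeR, no filter, a pseudocount of 0.25, quantile normalization and the replicate block left all 19 counts of calls within 1.5 times. edgeR, the identical columns as 2 libraries, voom with treat and the exclusion of the pair of 72 h libraries were chosen after the results were seen, the other alternatives before. Among the named-model results the block changed only 1 call, given next. After removing group means, same-numbered libraries correlated from -0.362 to 0.382. All were positive for glucose against no carbon at 72 h (0.0803, 0.264 and 0.234), but not in most comparisons. No steady pairing by number was seen, though so few libraries per group cannot exclude one. The models that lost their call were, in cellobiose against glucose at 15 h, jgi_Pospl1_129282_estExt_fgenesh3_pg_C_1940024 (adjusted p 0.0517 with only these groups in the fit, up to 0.292 without a replicate) and jgi_Pospl1_130338_estExt_fgenesh3_pg_C_2750003 (0.0599 with no filter, 0.0808 with the pseudocount of 0.25, 0.0821 with only these groups, 0.0638 with the block, 0.0593 by edgeR, up to 0.392 without a replicate). Restricting the fit to the compared groups moved 10 of the 19 counts by more than 1.5 times. Fold changes are the same in that fit, so only the estimated spread and the libraries behind it differ. The count rose from 3852 to 6813 for no carbon over time, with a mean r of 0.992 and 0.988 within groups. It fell from 3432 to 1323 for aspen at 72 h, with 0.942 within aspen. The shared spread may thus call too many models in loose groups and too few in tight ones. The files bound what can be said of the models, since no names are paired with them; depth of 7.18 M reads in aspen 72 h replicate 1 and n = 2 in cellobiose at 15 h bound small changes.

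With only the compared groups in the fit, counts were 4559 for cellobiose and 1074 for aspen at 15 h, 1323 for aspen at 72 h, 1389 for cellobiose against glucose and 1712 for aspen against glucose at 72 h. Over time they were 6813 for no carbon, 1880 for glucose, 6139 for cellobiose and 3730 for aspen, and 5470 for the cellobiose interaction. With the identical columns as 2 libraries, cellobiose at 15 h had 3163 and cellobiose against glucose 78. Without aspen 72 h replicate 3 and glucose 72 h replicate 1 the counts were 3856 for glucose, 3324 for cellobiose, 936 for aspen and 3945 for aspen against cellobiose at 15 h, and 3992 for the cellobiose interaction. voom with treat called, with 24 and 23 libraries, 175 and 170 in glucose, 204 and 147 in cellobiose and 131 and 121 in aspen at 15 h. At 72 h it called 804 and 753, 806 and 766, and 141 and 136.

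Asking for a 2-fold change in both, glucose and cellobiose shared 173 risen and 502 fallen models at 15 h (9.27 and 37.5 for independent lists), glucose and aspen 7 and 64 (6.19 and 7.25), and cellobiose and aspen 30 and 85 (6.10 and 8.30). At 72 h these were 754 and 974 (119 and 209), 150 and 381 (64.2 and 105.3), and 199 and 261 (66.3 and 96.4).

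Leaving out 1 replicate at a time gave 1160 to 2386 models for glucose, 642 to 1705 for cellobiose and 443 to 487 for aspen at 15 h. At 72 h the ranges were 4374 to 6118, 4171 to 4691 and 1936 to 4689. Cellobiose against glucose ran from 37 to 46 at 15 h and 925 to 3261 at 72 h. Aspen against glucose ran from 2268 to 3397 and 3532 to 4526, and against cellobiose from 1034 to 2724 and 3876 to 5003. Over time the ranges were 2815 to 3292 without carbon, 2908 to 4177 in glucose, 2029 to 3012 in cellobiose and 4635 to 5833 in aspen. The interactions ran from 1388 to 2899 for glucose, 1630 to 2406 for cellobiose and 659 to 2289 for aspen.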

Other observations

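All tests in this part were chosen only after the results were seen. At 72 h 670 models were higher in all 3 carbon sources than without carbon and 612 lower; at 15 h 18 were higher in all 3, and those lower in all 3 made up 12.7% of the 907 that fell in both sugars. A further 979 were called higher and 983 lower in both sugars with no call in aspen at 72 h, and 454 and 524 in aspen with no call in the sugars. At 15 h 149 models rose and 85 fell in aspen with no call in the sugars. A missing call does not show that a model was unchanged. Of the 55 models that rose in both aspen and cellobiose at 15 h, 43 were higher in cellobiose and 37 in aspen at 72 h.

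Levels of a few models over the groups were as follows. jgi_Pospl1_106359_fgenesh3_pg_24__68 stood at 31.3 ± 1.92 normalized CPM (SD, n = 3) without carbon at 15 h and 6189 ± 734 at 72 h, with 129 ± 3.89 in cellobiose and 13647 ± 2604 in aspen at 72 h. jgi_Pospl1_126338_estExt_fgenesh3_pg_C_1810001 was low in all 3 carbon sources at 15 h, at 0.774 ± 0.112 in aspen, 2.33 ± 0.686 in glucose and 1.64 ± 0.931 (n = 2) in cellobiose against 34.8 ± 11.3 without carbon, and stood at 533 ± 14.5 without carbon, 520 ± 18.6 in aspen and 170 ± 57.8 in glucose at 72 h. jgi_Pospl1_115648_estExt_Genewise1Plus_C_1530060 rose in cellobiose from 570 ± 36.1 (n = 2) to 8068 ± 1772 (n = 3) and in glucose from 30.97 ± 5.48 to 1084 ± 216, with 2279 ± 795 in aspen at 72 h.

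Aspen 72 h replicate 3 had reads in 12292 models, fewer than the other aspen 72 h libraries. Lower sequencing depth was unlikely, because its 13.7 M reads exceeded those of both others. A wrong group label was also unlikely, with a mean correlation of 0.923 to its own group and at most 0.884 to any other. Over models at 0.5 to 5 normalized CPM in the others, its mean level was 1.12 times theirs. This ratio was 1.086 and 1.1995 for replicates 1 and 2, so it does not set replicate 3 apart. Of the 4713 models, 1278 (27.1%) were listed at 0 where 0.790 would be by chance. The shares were 2.36% and 1.39% in replicates 1 and 2, whose reference libraries include replicate 3. The number at 0 was 1618 times the chance number in replicate 3, and 14.09 and 32.76 times in replicates 1 and 2. The chance number was thus too low in all of them. The share at 0 still sets replicate 3 apart, and few distinct RNA molecules behind its reads stays a candidate explanation.

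A hypothesis was that the models higher in cellobiose than in glucose at 15 h mark a response to cellobiose that aspen shares. Of these 42, 41 had risen in aspen; 0 of 10000 lists matched on level reached 41 and the highest reached 9, so a preference of both tests for abundant models was unlikely to account for it. Without the repeated cellobiose library the share was 100% (38 of 38), so that library alone was unlikely to decide it. At 72 h 92.9% of the 42 were again higher in cellobiose, which a response to cellobiose would give but lowering by glucose would give as well. Against no carbon, glucose lowered 33 of them at 15 h and 25 at 72 h, while cellobiose raised 25 and 34. The 15 h sugar libraries chose the 42 models, which favours such counts at 15 h, whereas the 72 h counts use other libraries. Both may therefore contribute, and which sugars reach the fungus from aspen was not measured.

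Models next to each other in the deposited order tended to change together in aspen at 15 h, with r = 0.107 between adjacent models against at most 0.0378 in 1000 permuted orders. The correlation fell to 0.0406 at 2 models apart, still above the highest permuted order (0.0397). Its mean at 3 to 5 apart was 0.0135, under the highest permuted order (0.0173) but reached by only 6 of the 1000. These values do not exclude a response of wider neighbourhoods. A gene split over adjacent models, reads shared by overlapping neighbours and a joint response of neighbouring genes cannot be told apart from the mean of 0.0135, which rests mostly on the 0.0300 at 3 apart, against 0.00817 at 4 and 0.00234 at 5.

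The call counts of comparisons with 3 libraries per group were set against all other splits of the same 6 libraries. There are 10 such splits, of which 1 is the real one, too few for a share under 0.05. Every other split mixes both real groups, so a real difference goes into the spread and lowers the count. These counts therefore do not decide on a division of the libraries by chance. The highest other split called 0 models for glucose (2248 real), aspen (598) and aspen against glucose (3383) at 15 h. At 72 h it called 0 for glucose (5491), cellobiose (5254), aspen (3432), cellobiose against glucose (2278) and aspen against cellobiose (4977). It called 0 for no carbon over time (3852), 1 for aspen over time (5622), 1209 for glucose over time (3765) and 2598 for aspen against glucose at 72 h (4224). The last of these joined glucose 72 h replicates 1 and 2 with aspen 72 h replicate 3.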
